A study of Mus musculus with 3 samples.

How the data were processed

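The series holds 3 libraries of polyadenylated RNA from mouse bone-marrow-derived macrophages, prepared from 1 µg of RNA each, per the labels. They carry the same treatment (100 ng/ml lipid A for 12 h, washout for 12 h, 100 ng/ml lipid A for 480 min) and the labels' biological replicate numbers 1, 2 and 3, so they form 1 group and no contrast between conditions exists. The replicate numbers pair nothing. The sequencer, read length, strandedness and aligner are not given in the sources used here.

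Each library came with 2 quantifications of mm10 transcripts in the GENCODE M21 annotation, per the notes deposited with the files. The first gives genes and transcripts, was made from alignments to the transcriptome, and has the column layout of RSEM. The second gives transcripts, was made from the reads against an index of M21 transcripts, and has the column layout of kallisto. Neither tool nor its version is named there, so both are called by their order here. Per the file headers, the deposited first tables hold expected counts, which share a read among the transcripts it could come from, so they need not be whole, and the deposited second tables hold estimated counts of the same kind. Per the file headers, both deposited kinds of table also hold TPM, in which counts were divided by effective transcript length and scaled to a fixed sum per library. Per the file headers, the deposited first gene tables hold FPKM, a length-scaled value proportional to TPM within a library. Per the file headers, the deposited first transcript tables also hold each transcript's percent of its gene (isoform percentage). In both, how reads shared by near-identical sequences were divided is a model estimate, which can move levels of pseudogenes, ribosomal proteins and mitochondrial genes.

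Gene tables held 55536 annotated genes (22028 protein-coding) and 26345 other entries. Of the latter, 26248 bore numeric names and 97 were external controls (spike-in sequences and phage PhiX). These other entries took 0.0875%, 0.0464% and 0.0636% of the expected counts of replicates 1, 2 and 3 and were left out of tests and of the library sizes used in them. The second quantification was summed to genes through M21, and 86 genes had no transcript in its index. Gene names, coordinates, GC content and transcript sequences came from GENCODE M21 on mm10. Expected counts totalled 24596382, 54016971 and 43127749 with these other entries included, and percentages of counts are of these totals. Expected counts were rounded to whole numbers for count tests. A gene at 0 counts was given an upper limit of 3 counts in each library, which with the gene's length and the library's depth gives a TPM floor. Floors and such limits cover counting error only.

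Gene lists (38, of which 21 pathways and 13 other cell types, the rest housekeeping, stress, sex-linked and mitochondrial genes), 6 pairs of lists and 16 pairs of genes were fixed first. Of 600 list genes, 599 were found by symbol in M21. List levels were medians of log2(mean TPM + 1) minus the median of 10350 protein-coding genes at 1 TPM or more in at least 1 library. Each of 37 lists (sex-linked genes left out) was tested against 100000 random lists of its size, two-sided, with Benjamini-Hochberg adjustment over lists and a threshold of 0.05. The SD beside a list is over its 3 per-library values, which were computed in the same way in each library and need not centre on the value of the mean. List pairs were compared by 100000 permutations of list labels over genes, two-sided, adjusted over the 6 pairs. Gene pairs were log2 ratios of TPM + 0.1 within a library, called separated with 1 sign in all 3 libraries and a mean beyond 3 SD. List shifts were median deviations of log2(TPM + 1) from the 3-library mean, as percentiles among 10000 random lists matched in 20 expression bins. From all deviations of a library the median deviation of its detected genes was first subtracted.

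Counting noise was tested per gene by a chi-square test of homogeneity on TMM-scaled library sizes, after edgeR's filterByExpr kept 11932 genes. TMM factors were 1.03, 0.865 and 1.12. Excess variance was tested with edgeR's quasi-likelihood fit with an intercept, comparing each gene's residual variance with the trended prior by an F test, one-sided. Quantifications were compared by limma on the within-library log2(TPM + 1) differences of 10203 protein-coding genes with a mean of at least 1 TPM in either, calling an adjusted p under 0.05 and a mean difference of at least 1. Dominant transcripts were compared for genes with a mean of at least 10 TPM. Correlations between libraries or quantifications are across genes of log2(TPM + 1), and genes are not independent replicates.

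Genes named in the text followed a fixed rule. It took up to 6 highest and 3 lowest members of each list, all sex-linked genes, all genes of the gene pairs, and the 15 most abundant nuclear protein-coding genes other than ribosomal proteins. It also took the 15 most variable genes past the excess-variance test (0 were found), the 10 largest differences between quantifications, and the 5 most abundant genes outside nuclear protein-coding ones. It gave 343 genes, of which the text names a part that was picked after the values were seen. Of the whole, 1 separated gene pair and 1 list member were left out on purpose and are not reported here. The genes in the last part of the text were chosen after their values were seen. The test of a scale difference first counted genes still called after centring, and that of other cell types first used percentiles over all list members, undetected ones included. Both were replaced, with the values set for each outcome, after their results were seen.

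Alternatives were other pseudocounts, TPM minimums, FPKM, CPM, the second quantification, other backgrounds, the mean in place of the median, DESeq2 size factors, total counts, no count filter, a mean count of at least 50, limma-voom, other thresholds, and leaving out each replicate in turn. Added after the data were seen were random lists matched also on GC content in 10 bins, robust variance shrinkage in limma, a difference of at least 1 in each library, and centring on each library's median.

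List levels, list shifts, the counting-noise and excess-variance tests and the comparison of quantifications were tested on simulated data, while list pairs, gene pairs and dominant transcripts were not. With counts drawn from the real means and no added variance, 0 of 11886 genes were called by the counting-noise test and 0 by the excess-variance test. With a coefficient of variation of 10% and no changed gene the counting-noise test called 6788 of 11875, so it responds to any variance beyond sampling. With a coefficient of variation of 10% and 200 changed genes among 11873, the excess-variance test recovered 31% of the 2-fold and 100% of the 4-fold changes with 0 false calls. With no added variance it recovered 70% and 98% among 11866 genes. The real coefficient of variation was 36.1%, above the simulated one, so recovery in the real data was not measured. The comparison of quantifications recovered 100% of 200 genes changed 3-fold among 10203, with 0 false calls. That simulation gave all genes the same noise, smaller than the pooled SD of 0.31 log2 units in the real data, and no scale shift between libraries. The genes called in the real data had a median SD of 0.72 over libraries, so the rate of false calls there was not measured. Of 200 random lists of 20 genes 3.0% had a p under 0.05, and 100% of 20 lists drawn from the most abundant genes were called. All these lists were drawn from detected genes, so the 3.0% does not cover lists with undetected members, such as the marker lists. A chemokine list shifted by 0.8 log2 units in 1 library was found, and 7.41% of the 108 other values lay outside the central range.

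R 4.3.3 was used with edgeR 4.0.16, limma 3.58.1 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.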

Results

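Polyadenylated RNA was sequenced from bone-marrow-derived macrophages of C57BL/6J mice, primary phagocytes grown from marrow precursors. The labels describe a pre-treatment with 100 ng/ml lipid A for 12 h, a washout of 12 h and a second exposure to 100 ng/ml lipid A for 480 min. Lipid A is the membrane-anchoring part of bacterial lipopolysaccharide and the part sensed by Toll-like receptor 4 (TLR4). The treatment fields of the same labels name lipoprotein A, and lipid A is used here after the written description. The 3 libraries, numbered biological replicates 1, 2 and 3, form 1 group. No untreated or once-stimulated library was analysed here, so levels, comparisons within a library and the spread between libraries are given, and no effect of the stimulation. The labels share 1 donor record and do not say whether the replicates came from separate animals, so the spread may be technical. Replicate 1 held 24596382 expected counts, replicate 2 held 54016971 and replicate 3 held 43127749. Levels are in TPM, a transcript abundance corrected for transcript length and library size, given as mean ± SD over the 3 libraries (n = 3) unless a single library is named, and coordinates are on mm10.

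Which transcripts filled these cells was asked first. Fth1 (ENSMUSG00000024661.7, chromosome 19, 9980598 to 9985098, plus strand), the ferritin heavy chain that stores iron, was the most abundant nuclear protein-coding transcript at 55491 ± 12053 TPM. The chemokine Ccl5 (ENSMUSG00000035042.2, chromosome 11, 83525778 to 83530518, minus strand), which attracts T cells and monocytes, followed at 22893 ± 14580 TPM. B2m, the light chain of class I antigen-presenting molecules, stood at 19517 ± 7386 TPM and the acute-phase protein Saa3 (ENSMUSG00000040026.8, chromosome 7, 46711998 to 46715700, minus strand) at 15301 ± 5759 TPM. Behind them came the actin-binding peptide Tmsb4x (12620 ± 3669 TPM), the ferritin light chain Ftl1 (12217 ± 8265 TPM), lysozyme Lyz2 (9400 ± 1767 TPM) and the membrane glycoprotein Gpnmb (8727 ± 8077 TPM). The remaining leaders were Actb, H2-K1, the lysosomal proteins Psap, Ctsb and Ctsd, the chemokine Cxcl10 (4232 ± 2061 TPM) and Itm2b (4092 ± 1304 TPM). This order is that of the means and did not hold in each library, since in replicate 2 Ccl5 (6168 TPM) lay below B2m (27851 TPM), Gpnmb (18004 TPM) and Tmsb4x (8428 TPM), and the place of Gpnmb rested on that library. At least 1 TPM was reached in all 3 libraries by 9439 protein-coding genes, with 10023 in replicate 1, 9660 in replicate 2 and 10062 in replicate 3. Of the sex-linked genes, Xist was read at 56.1 ± 6.99 TPM and its antisense partner Tsix at 0.01 ± 0.01 TPM. Ddx3y had 1 count in replicate 3, and Kdm5d, Eif2s3y and Uty had 0 counts in each library, which allows at most 0.174 TPM for Eif2s3y and 0.065 TPM for Uty in replicate 1.

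Where gene programmes lay among the transcripts of these cells was asked next, with lists fixed before the data were examined. Interferon-stimulated genes, the antiviral programme switched on by type I interferon, were high as a group. All 43 members reached 1 TPM in every library, 36 reached 100 TPM and 8 reached 1000 TPM. The membrane restriction factor Ifitm3 (3403 ± 1614 TPM), viperin Rsad2 (3232 ± 999 TPM), the ubiquitin-like Isg15 (2988 ± 1699 TPM) and the interferon regulator Irf7 (2538 ± 387 TPM) led the list, and Irf9 (71.7 ± 7.26 TPM) and Oas2 (72.2 ± 8.35 TPM) were its lowest members. The median of the list lay 5.04 ± 0.08 log2 units above that of the 10350 detected protein-coding genes, whose own median was 15.1 TPM. Lysosomal genes (5.22 ± 0.14, with Psap, Ctsb and Ctsd at 6756 ± 2128, 6048 ± 2551 and 5304 ± 2075 TPM) and macrophage identity genes (5.16 ± 0.06, with Fcer1g at 3999 ± 468 TPM and Adgre1 at 1806 ± 496 TPM) stood as high. Antimicrobial effectors (3.97 ± 0.42) reached 1 TPM in every library for 25 of 32 members. They included Saa3, the pore-forming protein Mpeg1 (1579 ± 304 TPM), the itaconate-producing enzyme Acod1 (2833 ± 1051 TPM) and the fungal-sensing lectin Clec4e (1044 ± 401 TPM), whereas Camp, Ltf, Pglyrp1 and Ptx3 stayed under 1 TPM. Antigen presentation genes lay at 3.95 ± 0.65, with H2-K1 at 7798 ± 2111 TPM and the class II master regulator Ciita at 3.37 ± 2.22 TPM. Anti-inflammatory mediators lay at 3.68 ± 0.06, led by Gpnmb, followed by the galectin Lgals9 (853 ± 106 TPM), the checkpoint ligand Cd274 (790 ± 232 TPM), the annexin Anxa1 (360 ± 157 TPM), haem oxygenase Hmox1 (277 ± 50.8 TPM) and the interleukin-1 receptor antagonist Il1rn (257 ± 27.0 TPM), and with Il10 at 30.4 ± 6.48 TPM. For these 6 lists the adjusted p of the two-sided permutation test was 3.36e-05, which follows from the smallest value the resamples can give, 2.0e-05.

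Metabolic and signalling lists lay nearer the middle. Glycolysis stood 3.02 ± 0.41 log2 units above the detected genes (adjusted permutation p = 6.43e-05), with Gapdh at 1206 ± 162 TPM and Aldoa at 402 ± 184 TPM, and the lactate exporter Slc16a3 at 5.89 ± 5.29 TPM. The tricarboxylic acid cycle stood at 1.99 ± 0.08 (adjusted permutation p = 0.00134), led by Sdhb at 160 ± 57.7 TPM and Mdh2 at 140 ± 28.6 TPM. Cholesterol handling stood at 1.69 ± 0.01 (adjusted permutation p = 0.00587), with the lipid carrier Apoe at 3311 ± 329 TPM and the oxysterol-producing enzyme Ch25h at 7.50 ± 9.70 TPM. Inflammasome and lytic cell death genes stood at 1.85 ± 0.15 (adjusted permutation p = 0.00269), led by Casp1 (381 ± 67.7 TPM) and Casp4 (219 ± 16.6 TPM). Arginine, nitric oxide and redox genes stood at 1.41 ± 0.46 (adjusted permutation p = 0.0270), with the peroxidase Prdx1 at 1408 ± 288 TPM and mitochondrial superoxide dismutase Sod2 at 1154 ± 415 TPM. That call was lost without replicate 1, at 1.10 with an adjusted permutation p of 0.0849, and with the mean of log2 values in place of the median, at 0.87 and 0.101. The lowest adjusted p of this list over its alternatives was 0.000174. Negative regulators of inflammatory signalling stood at 1.82 ± 0.31 (adjusted permutation p = 0.00074). The phosphatase Ptpn6 (486 ± 10.1 TPM), the repressor Atf3 (320 ± 38.4 TPM), Trim30a (316 ± 7.93 TPM) and the A20-binding protein Tnip3 (311 ± 21.8 TPM) led it, and Cish, Sigirr and Il1rl1 were its lowest members, with means under 1 TPM. The TLR4 receptor and its signalling chain reached 1 TPM in every library for all 26 members, with Cd14 at 330 ± 209 TPM, Myd88 at 139 ± 32.3 TPM and Tlr4 at 32.7 ± 1.14 TPM, and did not separate from the detected genes (0.87 ± 0.17, adjusted permutation p = 0.102). Neither did eicosanoid synthesis (0.89 ± 0.28, adjusted permutation p = 0.235, led by Alox5ap at 168 ± 30.5 TPM), dissociation and stress genes (0.52 ± 0.11, 0.408, led by Dnaja1 at 427 ± 145 TPM) or hypoxia and angiogenic factors (-0.94 ± 0.18, 0.153, with Mif at 163 ± 112 TPM and Vegfa at 16.0 ± 2.03 TPM). With all annotated protein-coding genes as the background TLR4 signalling (4.51, adjusted permutation p = 0.000139), eicosanoid synthesis (4.52, 0.00775) and stress genes (4.15, 0.00460) did separate. Eicosanoid synthesis lay at 0.27 without replicate 1 (adjusted permutation p = 0.713) and at -0.32 with the mean of log2 values (0.609).

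Inflammatory cytokines and chemokines were measured next. Tnf (ENSMUSG00000024401.14, chromosome 17, 35199381 to 35202007, minus strand), the early inflammatory cytokine, stood at 390 ± 274 TPM, the interleukin-27 subunit Ebi3 at 251 ± 76.0 TPM, Il15 at 209 ± 73.7 TPM and Il1b at 185 ± 92.6 TPM. Il6 (ENSMUSG00000025746.11, chromosome 5, 30013114 to 30019981, plus strand), the acute-phase cytokine, stood at 24.7 ± 33.2 TPM, and Il23a, Il19, Lif and Il33 stayed under 1 TPM. Of 21 measured cytokines 14 reached 1 TPM in every library, and the list did not separate from the detected genes (-0.46 ± 1.10, adjusted permutation p = 0.408). Without replicate 1 it lay below them, at -1.27 with an adjusted permutation p of 0.0253, against 0.0517 to 0.890 under the other alternatives. Chemokines stood at 2.17 ± 0.61 (adjusted permutation p = 0.000247). Besides Ccl5 and the interferon-induced Cxcl10, the monocyte and macrophage attractants Ccl3 (1985 ± 890 TPM), Ccl7 (1832 ± 613 TPM), Ccl2 (1343 ± 803 TPM) and Ccl4 (1178 ± 753 TPM) exceeded 1000 TPM on average. The neutrophil attractant Cxcl2 stood at 49.2 ± 61.8 TPM, and Ccl17, Cxcl5 and Cxcl13 had 0 counts in each library, which for Ccl17 allows at most 0.680 TPM in replicate 1. Classical activation genes stood at 1.84 ± 0.66 (adjusted permutation p = 0.00299), with Cxcl10, Tnf and the co-stimulatory receptor Cd40 (333 ± 86.7 TPM) among its highest members. Alternative activation genes, the programme linked to interleukin-4, lay at -2.49 ± 0.24 (adjusted permutation p = 3.36e-05). Among their 21 members, 8 stayed under 1 TPM in every library, Arg1 and Retnla had 0 counts, and Tgm2 (92.8 ± 25.9 TPM), the receptor chain Il4ra (89.2 ± 24 TPM) and the mannose receptor Mrc1 (15.8 ± 4.46 TPM) were detected. Cell cycle genes lay at -1.62 ± 0.20 (adjusted permutation p = 0.0036), with the replication clamp Pcna at 190 ± 37.7 TPM and the mitotic genes Plk1, Bub1 and Ccnb2 at means under 1 TPM. Against all annotated protein-coding genes both calls ended and both signs turned, at 1.14 (adjusted permutation p = 0.640) for alternative activation and 2.02 (0.336) for cell cycle genes. Secreted proteases and matrix genes lay at -1.04 ± 0.40 (adjusted permutation p = 0.0765), with osteopontin Spp1 at 906 ± 352 TPM and Mmp9 at 0.41 ± 0.208 TPM. They passed without replicate 1 (-1.33, 0.0261) and in the second quantification (-1.19, 0.0414), with the adjusted permutation p of the other alternatives between 0.0642 and 0.609.

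Markers of 13 other cell types were measured as a check on the culture, and every such list lay below the detected genes (adjusted permutation p = 3.36e-05 each). Endothelial markers lay at -3.14, osteoclast markers at -3.23, megakaryocyte markers at -3.41, haematopoietic progenitor markers at -3.66, T cell markers at -3.75 and neutrophil markers at -3.79. Dendritic cell and fibroblast markers lay at -3.80 each, mast cell and basophil markers and B cell markers at -3.98, natural killer cell markers at -3.99, eosinophil markers at -3.99 and erythroid markers at -4.01. Single members stood out. The adaptor Blnk (179 ± 25.0 TPM), the platelet factor Pf4 (110 ± 25.8 TPM), the granulocyte colony-stimulating factor receptor Csf3r (101 ± 14.4 TPM) and the interferon-responsive surface protein Ly6a (463 ± 292 TPM) were well expressed, while Ly6g, Cd79a, Nkg7, Epx and the globins Hbb-bt and Hba-a1 were listed at 0 TPM. Housekeeping genes (3.79 ± 0.11, led by B2m, Actb and Eef1a1) and mitochondrially encoded messenger RNAs (7.73 ± 1.95) lay above the detected genes, each with an adjusted permutation p of 3.36e-05. The mitochondrial value was raised by replicate 2 and was 5.79 without it. By library it lay at 5.88, 9.22 and 5.80 in replicates 1, 2 and 3. In all, 16 of 37 lists lay above and 15 below. With all annotated protein-coding genes as the background 19 lay above and 0 below, and the marker lists had an adjusted permutation p of 0.313 to 0.957, since most such genes are near 0 TPM. The tests draw on genes, which are not independent replicates, and several lists were made of genes that macrophages are known to express.

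**Figure D1:**
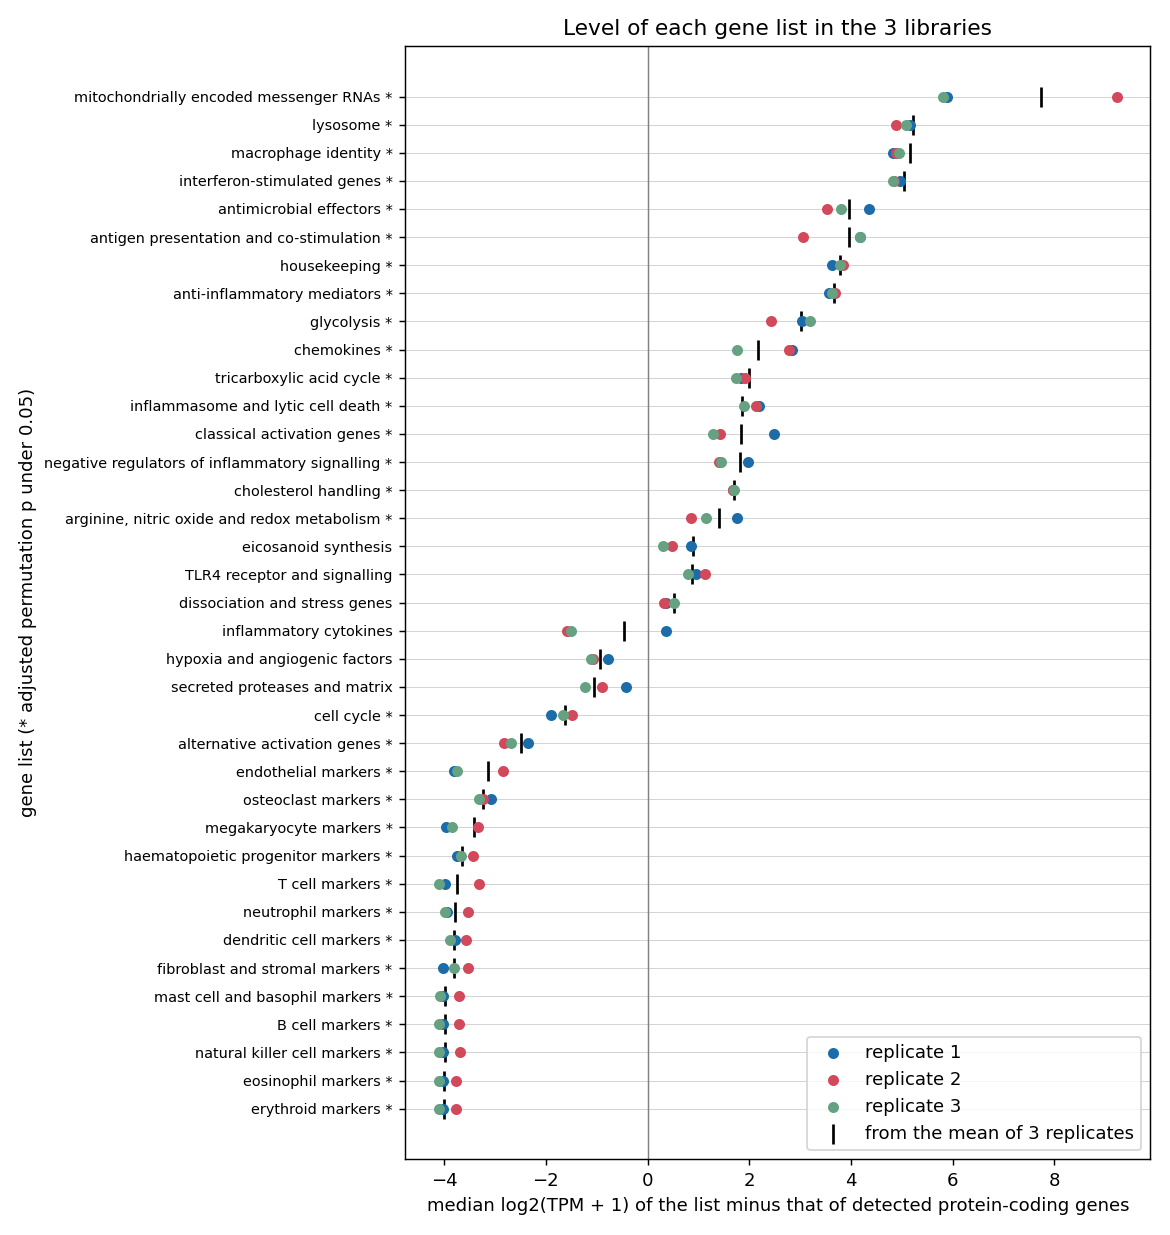
Median log2(TPM + 1) of each gene list minus that of detected protein-coding genes on the horizontal axis, with 1 point per library and a bar for the value from the 3-library mean. Lysosomal, macrophage identity and interferon-stimulated genes lie at 5.04 to 5.22, the markers of other cell types at -4.01 to -3.14, and the points of inflammatory cytokines are spread on either side of 0.

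Gene programmes were then set against each other within the same libraries. Interferon-stimulated genes exceeded inflammatory cytokines by 5.50 ± 1.01 log2 units (adjusted permutation p = 6.0e-05), and classical exceeded alternative activation genes by 4.33 ± 0.44 (adjusted permutation p = 0.00066). Antimicrobial effectors over cytokines (4.43 ± 0.71, adjusted permutation p = 0.0910), glycolysis over the tricarboxylic acid cycle (1.03 ± 0.49, 0.0910), chemokines over cytokines (2.63 ± 0.94, 0.244) and negative regulators over TLR4 signalling genes (0.95 ± 0.36, 0.260) kept their sign in all 3 libraries and did not pass the test. In all, 2 of 6 pairs passed. Restricted to members at a mean of at least 1 TPM, 4 passed, with antimicrobial effectors (2.91) and chemokines (3.12) over cytokines at an adjusted permutation p of 0.0185 each. The differences of the other pairs that passed were smaller there, at 3.54 (adjusted permutation p = 6.0e-05) for interferon-stimulated genes over cytokines and 2.03 (0.0185) for classical over alternative activation genes. Antimicrobial effectors over cytokines also passed without replicate 1 (5.18, adjusted permutation p = 0.0173) and with the mean of log2 values (2.63, 0.0294), and the range of that p over all alternatives was 0.0173 to 0.110.

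Pairs of genes with related roles were compared within each library, where scaling cancels. Nos2 (ENSMUSG00000020826.8, chromosome 11, 78920787 to 78960254, plus strand), which makes nitric oxide from arginine, stood at 77.2 ± 56.6 TPM. Its rival for the same substrate, Arg1 (ENSMUSG00000019987.9, chromosome 10, 24915221 to 24927484, minus strand), had 0 counts in every library, so Nos2 was at least 319-fold higher in each against a floor of 3 counts per library. The checkpoint ligand Cd274 exceeded its relative Pdcd1lg2 by 10.22 ± 0.88 log2 units, and Cxcl10 exceeded Cxcl2 by 7.13 ± 1.18. Ccl5 exceeded Ccl2 by 3.92 ± 0.93, and inducible Sod2 exceeded Sod1 by 2.46 ± 0.58. Against Tnf, Il6 stood at -4.82 ± 1.32 and Il1b at -0.97 ± 0.26. In all, 8 of 16 pairs, these among them, kept 1 sign in all 3 libraries with a mean above 3 SD. Ptgs2 over Ptgs1 (3.73 ± 2.04), Cd14 over Tlr4 (3.04 ± 1.2), Cd86 over Mrc1 (2.39 ± 1.00), Irak3 over Irak1 (1.78 ± 1.00) and Nfkbia over Nfkbib (1.35 ± 0.54) kept their sign but spread too widely. Il1rn over Il1b (0.58 ± 0.56) and Il10 over Il12b (-0.45 ± 0.82) changed sign between libraries, and for Arg2 over Arg1 no ratio is given because Arg1 had 0 counts and Arg2 at most 6. An exact sign-flip test over 3 libraries cannot go below p = 0.25, so none was used. Without replicate 2, 13 pairs met the rule, against 11 without replicate 1 and 7 without replicate 3. Cd274 over Pdcd1lg2 moved to 8.94 with pseudocount 1 and to 11.50 with CPM, and with CPM Ccl5 over Ccl2 moved to 2.92, Sod2 over Sod1 to 3.79, Il1b over Tnf to -1.31, Cd14 over Tlr4 to 1.64, Cd86 over Mrc1 to 1.28 and Il1rn over Il1b to 1.2.

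How far the replicates differed was asked by gene and by list. Mitochondrially encoded messenger RNAs took 6.86% of the counts in replicate 2 against 1.06% in replicate 1 and 1.13% in replicate 3. The oxidase subunit mt-Co1 stood at 28355 TPM in replicate 2 against 7034 and 7249 TPM in replicates 1 and 3. Ribosomal RNA other than mitochondrial went the other way, at 0.232% of the counts in replicate 2 against 3.21% and 1.97%. Mitochondrial ribosomal RNA was highest in replicate 2, at 0.342% of the TPM against 0.128% and 0.158%. Ccl5 (6168 against 32924 and 29588 TPM) and Ftl1 (2686 against 17396 and 16569 TPM) were low in replicate 2, and Gpnmb (18004 against 3259 and 4916 TPM) was high in it. Across 10003 genes Pearson's r of log2 TPM was 0.981 between replicates 1 and 3, 0.914 between 1 and 2 and 0.915 between 2 and 3. A 2-fold or larger difference separated 224 genes between replicates 1 and 3, 2319 between 1 and 2 and 2564 between 2 and 3. In the second quantification these counts were 450, 2118 and 2280. For pairs with replicate 1, the main direction of these differences depended on the quantification. Between replicates 1 and 2, 1752 genes were higher in replicate 1 and 567 in replicate 2, against 730 and 1388 in the second quantification. Between replicates 1 and 3, 135 were higher in replicate 1 and 89 in replicate 3, against 48 and 402. Between replicates 2 and 3, most were higher in replicate 3 in both quantifications. Counts differed by more than sampling noise for 10491 of 11932 genes (chi-square test of homogeneity, Benjamini-Hochberg adjusted), and by pair for 6695 of 12181 between replicates 1 and 3, 9121 of 11944 between 1 and 2 and 9696 of 12205 between 2 and 3, so no pair of libraries agreed within sampling noise. No gene passed edgeR's quasi-likelihood comparison of its variance with that of genes of like abundance, at a common biological coefficient of variation of 36.1%. At an unadjusted p under 0.05 there were 503 genes, and limma-voom called 0 with 517 at that level. Leaving out replicate 1, 2 or 3 gave 20, 7 and 11 calls at coefficients of variation of 40.9%, 20.5% and 41.3%, and 64 genes were called without the filter on low counts.

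By list, replicate 1 stood apart for several inflammatory lists, but not for TLR4 signalling (0.06), eicosanoid synthesis (0.003) or inflammasome genes (-0.0009). Deviations from the 3-library mean were centred in each library on the median of the detected genes. Above and below the mean are therefore relative to those genes. In replicate 1 cytokines lay 0.71 log2 units above the mean, with 17 of 21 members above it. Tnf was at 706 TPM in replicate 1 against 233 and 231 TPM in replicates 2 and 3, Il6 at 62.9 against 3.25 and 7.90 TPM, and Cxcl2 at 121 against 15.3 and 11.8 TPM. Prostaglandin synthase Ptgs2 was at 90 against 18.0 and 14.2 TPM and the immediate-early factor Junb at 224 against 28.7 and 94.1 TPM. Chemokines, classical activation genes and dissociation and stress genes each lay 0.44 above the mean in replicate 1, antigen presentation 0.33, arginine and redox genes 0.25, negative regulators 0.21 and antimicrobial effectors 0.19, while cell cycle genes lay at -0.27. In replicate 2 antigen presentation genes lay at -0.59 with 20 of 22 members below the mean, among them H2-D1 (1447 against 5174 and 5106 TPM) and Cd74 (303 against 794 and 965 TPM). Glycolysis lay at -0.41 and classical activation at -0.33 there, cell cycle genes at 0.33 and mitochondrial messenger RNAs at 2.01. In replicate 3 antigen presentation lay at 0.36 and cytokines at -0.46. Classical activation (-0.25), inflammasome (-0.23), chemokine (-0.21) and protease (-0.18) genes were below the mean as well. Mitochondrial messenger RNAs lay at -1.13 in replicate 1 and -0.97 in replicate 3. These were the 22 of 111 list medians in the lowest or highest 2.5% of 10000 random lists matched on expression, where 5.55 would be so by chance. In the simulated data 7.41% of 108 list medians without a shift lay there. Before centring, the deviations of a gene sum to 0 over the libraries, so a shift in 1 library forces opposite ones in the others, as for mitochondrial messenger RNAs, and the 22 are not independent. Matched on GC content as well, 28 lay there, and negative regulators in replicate 1, glycolysis in replicate 2 and chemokine, inflammasome and protease genes in replicate 3 no longer did. The expression bins were coarser in that matching, so these changes need not come from GC content. They describe these libraries and carry no p over conditions.

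**Figure D2:**
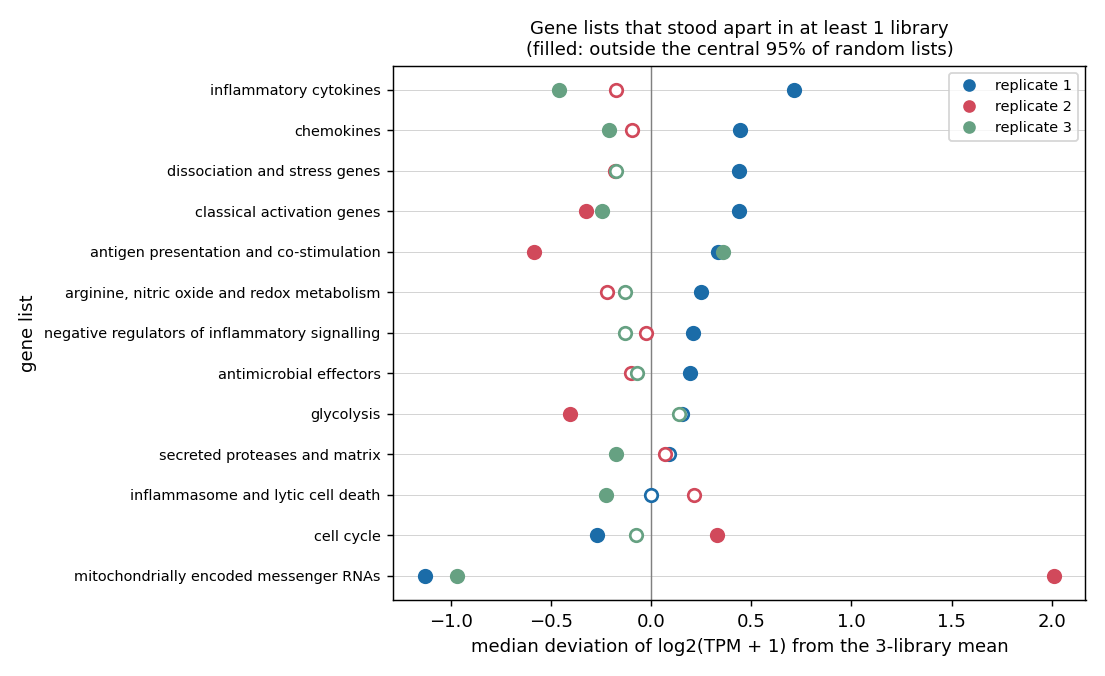
Median deviation of log2(TPM + 1) from the 3-library mean, centred on the detected genes of each library, on the horizontal axis for the gene lists that stood apart in at least 1 library, with filled points outside and open points inside the central range of random lists. Cytokines lie at 0.71 in replicate 1, and mitochondrially encoded messenger RNAs lie at 2.01 in replicate 2.

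**Figure D3:**
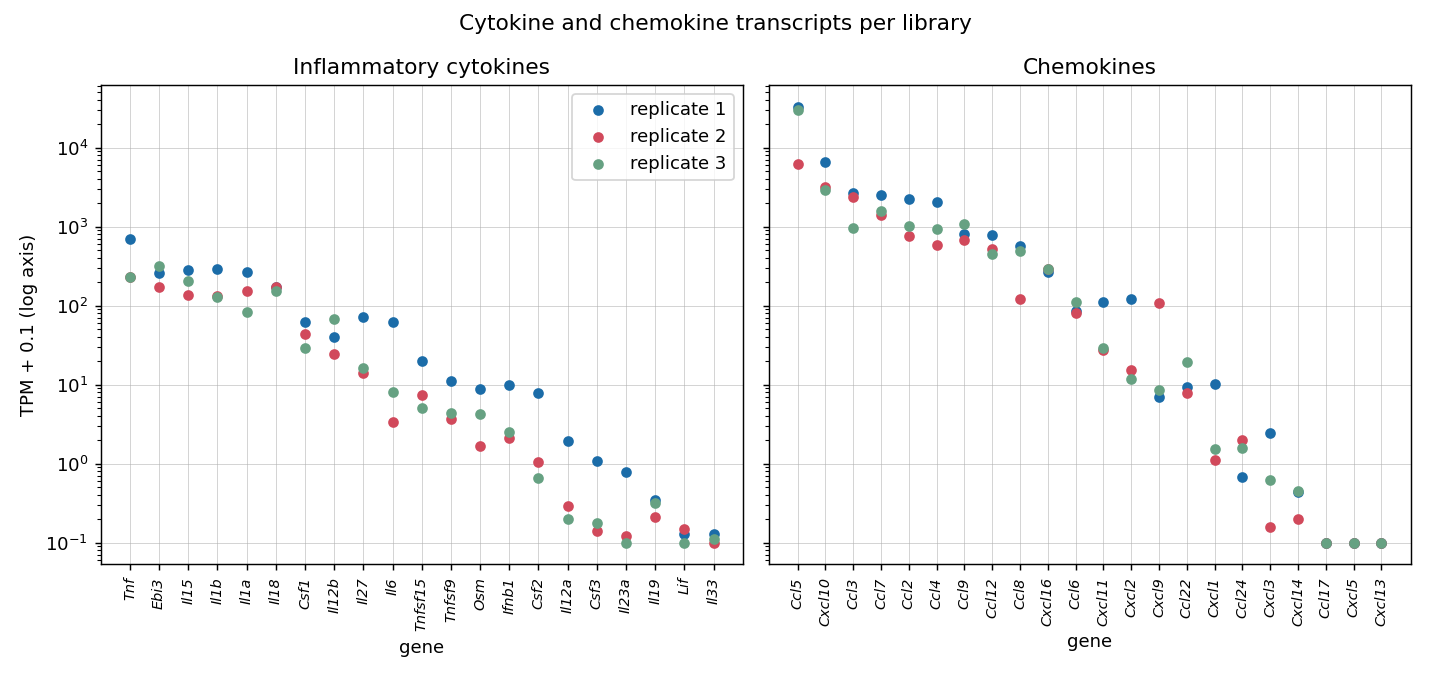
TPM + 0.1 of each inflammatory cytokine and chemokine on a log axis, with 1 point per library and genes ordered by mean level. Tnf reaches 706 TPM and Il6 62.9 TPM in replicate 1, above the points of replicates 2 and 3.

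Each library had been quantified in 2 ways, which allowed a check of which gene levels rest on the method. Klf10, a zinc-finger repressor induced by transforming growth factor beta, stood at 13.0 ± 4.96 TPM in the first quantification and 38639 ± 64199 TPM in the second. There, 1 transcript of 326 nt held 112763 TPM in replicate 1, 1614 in replicate 2 and 1502 in replicate 3, against 0 in the first. The ribosomal proteins Rps12 (596 ± 214 against 20.2 ± 2.20 TPM) and Rpl12 (155 ± 18.0 against 5.89 ± 3.72 TPM) were higher in the first, and the near-copy Rps12-ps3 (20.6 ± 25.5 against 600 ± 333 TPM) and mt-Atp6 (620 ± 773 against 8796 ± 10950 TPM) in the second. Gm17374 (435 ± 595 TPM), Gm17402 (135 ± 176 TPM), Olfr93 (129 ± 212 TPM), Gm11027 (124 ± 209 TPM) and Gm47283 on chromosome Y (43.5 ± 13.0 TPM) were read only in the second quantification, and Gm47283 shares 65.1% of its 31-base words with other genes. Levels of these 10 genes are uncertain, as are those of mt-Co3, which shares 99.9% of its words with other genes, and mt-Atp8, which overlaps mt-Atp6. Across 10203 genes the quantifications correlated at r = 0.981, 0.984 and 0.986 in replicates 1, 2 and 3, with median log2 differences (first minus second) of 0.42, -0.05 and 0.09. By limma, 169 genes differed by at least 1 log2 unit at an adjusted p under 0.05, 40 higher in the first and 129 in the second. The fit gave every gene 1 pooled SD of 0.31 log2 units, which understates the error of variable genes. With robust shrinkage 123 were called, 77 differed by at least 1 log2 unit in each library, and 85 were called after centring each library on its median.

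Among the 5890 protein-coding genes with several annotated transcripts and a mean of at least 10 TPM, 4172 (70.8%) had the same most abundant transcript in all 3 libraries. For 3639 (61.8%) it was also the same in the second quantification. Without replicate 2 the first share was 93.3% (5605 of 6010), against 73.2% without replicate 1 and 72.6% without replicate 3. Outside nuclear protein-coding genes, the ribosomal RNA CT010467.1 (16089 ± 13679 TPM) and the mitochondrial messenger mt-Atp8 (37226 ± 35778 TPM) were the most abundant, with mt-Co1 (14213 ± 12248 TPM). The mitochondrial-like pseudogenes Gm28661 (12902 ± 11887 TPM) and Gm10925 (9693 ± 9375 TPM) followed, and their levels are uncertain because they share sequence with mitochondrial genes. These ranks are of means and did not hold in each library. Ribosomal RNA other than mitochondrial held 29136, 1854 and 17277 TPM in replicates 1, 2 and 3, so that in replicate 2 it lay below mt-Co1. Mitochondrial genes held 2.72%, 17.1% and 4.10% of the TPM.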

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

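The tests of shared reads and of a scale difference between the quantifications, and the tests on cytokines in replicate 1, were chosen after those results were seen. No biological explanation was tested for any pattern beyond a mixture with other cell types, since the design has 1 group.

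Reads of the phage PhiX, a sequencing control and no part of the measured transcripts, were counted in each library above the 3 counts that a count of 0 allows. There were 21528 in replicate 1, 25075 in replicate 2 and 27427 in replicate 3, against library totals of 24596382, 54016971 and 43127749 expected counts.

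Replicate 2 stood apart from replicates 1 and 3, with 2319 and 2564 genes at a 2-fold or larger difference against 224 between the others (2118, 2280 and 450 in the second quantification), low Ccl5 and Ftl1, high mitochondrial messenger RNAs and a high Gpnmb. For depth, all libraries were thinned to the smallest. The SD of log2 ratios of replicate 2 over 1 was then 2.235 times that of replicate 1 over 3, against 2.236 before. These were well-counted genes, whose expected ratios thinning keeps, so that test could not point to depth and does not weigh on it. A few genes taking most of the counts would shift the rest by 1 factor, yet the ratio of SDs after median scaling was 2.24 over 5090 well-counted nuclear genes. GC content was related to the difference across genes (Spearman's rho -0.437, against -0.144 for replicate 1 over 3), and may account for part of it. Removing the trend left a ratio of 2.11, so a smooth trend on the mean GC content of each gene was not the whole. GC effects within transcripts were not tested. Transcript length tracked replicate 2 (rho 0.263) and also replicate 1 over 3 (0.232), so its part stays open, as rho lay between the values set for either outcome, and a difference in the cells, the RNA or the library preparation stays open.

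Inflammatory cytokines lay high in replicate 1, with Tnf, Il6 and Cxcl2 at their highest there beside Junb and Ptgs2. GC content did not account for it, since among lists matched on expression and GC content the list was at percentile 100. After thinning to the smallest library, the 13 best-counted cytokines still had a median log2 ratio of 1.04 over the mean of the others, with 10 higher. Thinning keeps the expected ratio of such genes, so that test could not point to depth and does not weigh on it. For neutrophils, the median log2 ratio of their 5 expressed markers over the mean of the others was -1.13, with 1 higher in replicate 1. That lay on the side set against neutrophils. The mean includes replicate 2, which stood apart, and replicate 1 was not compared with replicate 3 alone, so the value does not decide. Over all 13 markers, undetected ones included, the median deviations were -0.08, 0.20 and -0.24 in replicates 1, 2 and 3. Other leukocytes stay open, since only T cell markers had at least 3 expressed members (median -0.52), while dendritic cell (0.87, 2 of 2 higher in replicate 1), mast cell and basophil (1.21, 1 of 1), B cell (-0.37, 0 of 2) and natural killer cell markers (0 expressed) had too few, and a difference in timing or handling between the cultures may remain, as a hypothesis that was not tested.

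The 169 genes whose level depended on the quantification, such as Rps12, Rpl12 and mt-Atp6, overlapped another gene no more often than the other genes tested (50.9% against 55.8%, a ratio of odds of 0.822). Reads shared between near-identical copies are a candidate explanation for part, since 65 of the genes (38.5%) had at least 50% of their 31-base words in other genes, against 5.62% of the rest, a ratio of odds of 10.5. After centring each library, 163 of the genes (96.4%) still differed by at least 1 log2 unit. With median differences of 0.42, -0.05 and 0.09, centring could take few genes below 1, so this count was largely fixed in advance. Shifts of that size lie below the 1 log2 unit at which genes were called, so they cannot alone make up these differences. They did widen the spread, with a median SD over libraries of 0.26 before and 0.07 after centring for all tested genes. Only 71 were still called, at a median size of the difference of 1.57 before and 1.67 after centring for all 169 (median SD over libraries 0.72 and 0.69). Of the 98 lost, 92 kept a difference of at least 1, so their calls ended through the p of the new fit, which pooled SDs less. All 92 passed when the centred values were tested with the pooled SD of 0.31, but a difference of at least 1 passes there by construction. Of the 10 largest differences, 6 had under 50% shared words (Klf10 3.40%, Olfr93 4.46%, Gm11027 26.2%, Gm17374 29.2%, Gm17402 39.9% and Rpl12 49.8%) and stay open.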

How the results depend on the processing

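The lists matched on GC content, robust shrinkage, a difference of at least 1 in each library and centring were added after the data were seen. No paired analysis was possible because the series has 1 group. Counts of detected genes (6960 to 10066 against 9439), of lists above the detected genes (15 to 19 against 16) and of list shifts (27 to 31 against 22) stayed within 1.5 times under all alternatives run. With all annotated protein-coding genes as the background, whose median is near 0 TPM, 0 lists lay below in place of 15, and by that construction 8 values turned positive: cytokines 3.17, alternative activation 1.14, cell cycle 2.02, hypoxia 2.69, proteases 2.59, megakaryocyte 0.22, endothelial 0.50 and osteoclast 0.40. With the mean of log2 values, eicosanoid synthesis turned to -0.32, and the cause was not tested. Restricted to members at 1 TPM or more, 4 list pairs passed in place of 2, and 3 did with the mean of log2 values. Leaving out each replicate gave 7 to 13 separated gene pairs against 8, 6695 to 9696 genes beyond counting noise against 10491, and 7 to 20 genes above the variance trend against 0, where fewer libraries entered. Without the count filter 64 genes were above the trend, and the cause was not tested. At a mean of at least 1 TPM more genes entered, and 6404 and 5492 kept their dominant transcript against 4172 and 3639. The 169 genes that differed between quantifications became 258 with pseudocount 0.1, 322 at a difference of at least 1.5-fold, 59 with CPM of estimated counts, 60 at a mean of at least 10 TPM (fewer genes), 77 with a difference of at least 1 in each library and 85 after centring. Robust shrinkage gave 123, and apart from centring the causes of the others were not tested. Of the single values, 434 counted as kept, by direction and side of the threshold. Gene pairs, which have no test, counted there within 1 SD, whether or not the pair stayed separated. Of the others, 11 moved, 9 reversed, 10 gained and 12 lost their call. Among those reversed, alternative activation, cell cycle, megakaryocyte, endothelial and osteoclast lists also lost their call and are not among the 12. Depth limited the lowest genes, since 3 counts were worth 0.285 TPM of Arg1 in replicate 1 and 0.110 TPM in replicate 2.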

Other observations

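The genes below were chosen after their values were seen, and no test was run on them. Beyond the fixed lists, complement and membrane proteins of macrophages were among the most abundant nuclear transcripts. The complement chains C1qb (2422 ± 730 TPM, SD, n = 3) and C1qc (1539 ± 797 TPM) start the classical complement pathway. The membrane proteins Ms4a4c (2950 ± 447 TPM), Ms4a6c (1430 ± 179 TPM), Ms4a6d (1263 ± 115 TPM) and Ms4a7 (1138 ± 164 TPM) belong to 1 gene cluster on chromosome 19. The glycoprotein Cd52 (2933 ± 1196 TPM), the lipid-anchored Ly6e (3440 ± 1235 TPM) and the fatty-acid-binding Fabp5 (2564 ± 1175 TPM) stood as high. Lgals3bp (2080 ± 54.8 TPM) and the proton pump subunit Atp6v0c (1393 ± 54.6 TPM) varied little between libraries. The lysosomal protease Lgmn (1667 ± 283 TPM), the nucleotide hydrolase Samhd1 (1126 ± 170 TPM) and the secreted Fgl2 (1480 ± 300 TPM) were also high.

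Long non-coding RNAs were led by AW112010 (2032 ± 1159 TPM), an interferon-responsive transcript. The nuclear Malat1 stood at 339, 1391 and 419 TPM in replicates 1, 2 and 3 and its neighbour Neat1 at 269, 52.5 and 195 TPM, so that they differed in opposite directions in replicate 2. Mir155hg, the host of an inflammation-linked microRNA, stood at 48.4 ± 21 TPM. Gm10076 was at 985 ± 639 TPM in the first quantification and 1.63 TPM in the second. Transcripts under 300 nt held 1.68%, 10.4% and 3.21% of the TPM of replicates 1, 2 and 3 in the first quantification and 17.7%, 7.94% and 8.16% in the second. Cxcl9, an interferon-gamma-induced chemokine, was at 106 TPM in replicate 2 against 6.79 and 8.48 TPM in replicates 1 and 3, opposite to Ccl5.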
